A study of Homo sapiens with 19 samples.

How the data were processed

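RNA from 4 normal thyroids, 10 PTC and 5 ATC was measured on 19 arrays of spotted cDNA clones with 2 channels, each tissue against a pooled reference RNA of 3 thyroid cancer cell lines. Each array file held 18600 spots, of which 12483 carried clones, 6072 were blank and 45 were alignment marks. The image analysis program was not given in the sources used here, and no slide, print or scan batch was recorded.

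The deposited array files give each channel as an intensity, the mean of the signal pixels less the local background, together with the mean and SD of that background. Per the file headers, each channel also has a signal to noise score, and each spot has a quality score of its ratio between 0 and 1. The ratio in the deposited files is the Cy3 over the Cy5 intensity divided by 1 multiplier per array. The authors' value table for the series holds the log2 of such a ratio for 12483 spots and is not centred. Its columns equalled the array files within 1e-04 for 11 of 19 arrays, and 8 PTC columns (PTC 1 to 8) equalled none of the files. Over 2080 spots of high quality, 9 of 10 PTC columns followed their own file best (median r 0.499, against 0.163 for the best other file). These 10 columns included PTC 9 and PTC 10, which equalled their files, so their match was given. The 1 column that did not follow its own file best followed another PTC file better. The values were therefore rebuilt from the array files.

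Per the labels of the samples, the tissue was labelled with Cy3 and the reference with Cy5, whereas the series text names the dyes the other way round. The direction was checked with cell types that cell lines lack. The median log2 ratio of Cy3 over Cy5 for 19 fibroblast genes was 3.78 in normal thyroid, 2.30 in PTC and 3.52 in ATC, and was above 0 on all arrays, as was that of TG (6.95, 6.75 and 3.86). T and NK cell genes (26) had group medians of 0.42, 0.19 and 1.28, red blood cell genes (7) of 0.56, 0.17 and 1.28, and B and plasma cell genes (16) of -0.76, -0.28 and 0.27. Cy3 was therefore taken as the tissue.

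A spot was usable when its quality score was above 0. The deposited background-subtracted intensities were raised to a floor of 1 median background SD of their channel and array. The log2 ratio was normalized within each array by loess on the mean log2 intensity of the usable spots (span 0.3, 4 iterations), with no scaling between arrays. Spots of a clone were averaged, and a clone was kept if measured in at least 50% of the arrays of each group. Each gene was represented by the clone with the highest mean intensity. This left 6058 features, 4878 of them named genes and the others clones without a single gene symbol, with 7.67% of values missing.

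Gene names came from the platform's probe annotation and were brought to current symbols by gene id. Of the clone spots, 10133 had 1 symbol, 670 had several and 1680 had none; the last 2 kinds stayed in the fit as unnamed clones. There were 8380 genes named on the array, 749 of them with several clones. No genome came with the series, so no coordinates are given. A further 12 spots were left out by a rule that removes genes of the sex chromosomes tied to donor sex.

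A channel was called above background at a signal to noise score of at least 2. Where the tissue signal of a gene was above background on no array of a group, the fold is given as a bound against the lowest signal above background on those arrays. Arrays with a median tissue background SD of 30 or more were called high background arrays.

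A linear model over the 3 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated t tests for ATC minus normal, PTC minus normal and ATC minus PTC and Benjamini-Hochberg adjustment over all features of a comparison. A feature changed when its adjusted p was below 0.05, and the errors of gene changes are standard errors of the model. The 32 lists, 20 of pathways and 12 of cell type markers, were written before the data were examined. Lists with at least 3 measured members were tested with cameraPR at a correlation of 0.01 between genes, adjusted over lists, and again with camera at the correlation estimated from the arrays and with fry. The array scores of each list were compared with exact permutation tests, adjusted over 87 tests. The smallest p that these can give is 0.00794 for 5 against 4 arrays, 0.000999 for 10 against 4 and 0.000333 for 5 against 10. Data were handled with the R package data.table at version 1.17.8, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, figures were drawn with matplotlib 3.10.9, and statmod 1.5.0 was loaded by limma.

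Genes were named by a rule set beforehand: in each comparison the 6 largest rises and the 6 largest falls among genes that passed with non-overlapping groups, up to 4 passing members of each list with the largest change (or, where none passed, the measured member with the largest change), and 20 genes in every comparison. Of these 20, 13 were measured under a single symbol on enough arrays.

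The steps were tested on simulated data with 200 changed features per comparison. The noise was drawn independently for each feature and array, with 1 spread per feature for all 3 groups and no background class. These simulations could therefore not show false list calls that arise from correlated members. They could also not show false calls from unequal spread between groups, from high background or from normal arrays that share a donor. Changes of 1 on the log2 scale were recovered for 55%, 56.5% and 64% of features, changes of 2 for 91%, 95.5% and 91%, and changes of 0.5 for at most 0.5%, with at most 8.13% false calls. A list shifted by 0.5 was called in all 3 comparisons, with 0 of 28 other lists called. In simulations with no change, 1 feature was called in PTC versus normal and 0 in each other comparison.

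Shared changes of ATC and PTC against the same normal arrays were compared with 100 simulations of unchanged groups from shuffled residuals and with the normal arrays split into pairs. The numbers of the samples were not used to pair them: arrays of the same number in different groups had a median r of 0.00883 (13 pairs), against -0.00471 for 97 other pairs. Other splits of the samples were drawn 100 times per comparison with a fixed seed, the real one included.

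Alternatives fixed beforehand were normexp background correction (offset 50) or none, median centring within arrays, scaling between arrays, the authors' value table, no filter or features measured in every array, the mean of all clones of a gene, only the 2 groups compared, a trended and robust prior variance, array weights, a replicate block, and leaving out each array. Added after seeing the data were no floor or a floor of 2 background SDs, the value table centred on each column's median, the background class as a block, the low background arrays only (also with a correlation estimated from them), and the normal arrays averaged into 1 sample.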

Results

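Gene expression was compared in 19 pieces of thyroid tissue with 2-colour arrays of spotted cDNA clones. They were 4 normal thyroids, 10 papillary thyroid carcinomas (PTC) and 5 anaplastic thyroid carcinomas (ATC). Papillary carcinoma is the common, differentiated cancer of the thyroid follicle, and anaplastic carcinoma is its rare, undifferentiated and aggressive counterpart. Every tissue RNA was hybridised together with the same reference, a pool of RNA from the 3 thyroid cancer cell lines TPC1, BCPAP and ARO. All values are log2 ratios of tissue over reference, and a difference between groups of this ratio is written as a log2 change. The series title names proliferation and chromosomal instability in ATC as its subject, so genes of mitosis and DNA replication were among the 32 gene lists fixed before the data were examined.

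Signal over background set how much each array could show. Between 80.2% and 84.8% of clone spots were usable on the normal arrays, 62.6% to 80.2% on the ATC arrays and 44.8% to 84.0% on the PTC arrays. The 7 PTC arrays from PTC 2 to PTC 8 had a local background that varied by 35.8 to 53.9 intensity units (SD) in the tissue channel, against 9.7 to 17.5 on the other 12 arrays. The reference channel of these 7 arrays followed that of the normal arrays with a median r of 0.524 to 0.707 over spots, against 0.803 to 0.955 for the others. High and low background PTC arrays differed from each other in 408 of 6056 features, and no high background array held normal thyroid or ATC. The numbers of changed features and the means of called lists in comparisons with PTC are therefore given with all arrays and with the 12 low background arrays, of which 3 were PTC, an alternative added after the data were examined. Single genes and the members of lists are given with all arrays, and only some of them also with the low background arrays.

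The normal arrays were far more alike than the tumours. Pairs of normal arrays correlated over genes with r between 0.947 and 0.961, pairs of PTC arrays between 0.662 and 0.897, and pairs of ATC arrays between 0.695 and 0.837. The median SD of a gene was 0.182 in normal thyroid, 0.402 in PTC and 0.443 in ATC. The sample names number the normal thyroids 1 to 4, but 1 label field repeats the first one's name for all 4, so it stayed open whether they came from 4 donors. The p-values measure the spread between these samples, also for ATC versus PTC, since the fit pools the spread of all 3 groups. Counts against normal thyroid were therefore repeated with the 4 normal arrays averaged into 1 sample, which was then assumed to vary like the other groups.

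In ATC, genes of mitosis and DNA replication were higher than in normal thyroid, and genes of thyroid differentiation and epithelial adhesion were lower. The mean of the mitosis list was -3.25 ± 0.10 (SD, n = 4) in normal thyroid and -0.82 ± 0.42 (SD, n = 5) in ATC on the log2 ratio scale. The mean of the thyroid differentiation list was 4.87 ± 0.09 (SD, n = 4) in normal thyroid and 1.90 ± 0.66 (SD, n = 5) in ATC. Markers of macrophages and genes of glycolysis and the interferon response were also higher in ATC at the preset correlation, but these 3 lists did not pass with an estimated correlation (adjusted p = 0.204, 0.0680 and 0.406), nor did epithelial adhesion (adjusted p = 0.0680). At the level of single features, 1040 rose and 1095 fell among 6058 tested (limma, adjusted p below 0.05).

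Of the 43 measured members of the mitosis list, 37 rose in ATC and 1 fell against normal thyroid, and adjusted over the list alone 38 rose and 1 fell. Their mean log2 change was 2.45 (camera adjusted p = 1.98e-26, and adjusted p = 0.0237 with an estimated correlation, or 0.0807 with one estimated from the low background arrays). CEP55, which acts in the final separation of daughter cells, rose by 5.13 ± 0.46 (SE, adjusted p = 3.95e-07). ANLN, an actin-binding protein of the cleavage furrow, rose by 4.61 ± 0.70. PBK, a mitotic kinase, and BUB1, a kinase of the spindle checkpoint, were not above background in the tissue channel of any normal array. Their rise in ATC was at least 20.2-fold for PBK and at least 12.4-fold for BUB1 (adjusted p = 1.01e-07 and 1.03e-05). The kinase PLK1 rose by 3.33 ± 0.73 (adjusted p = 0.00224). The brightest clone of AURKA differed by 0.04 ± 0.29 (adjusted p = 0.925), whereas AURKA rose by 1.58 as the mean of all its clones (adjusted p = 8.57e-05) and by 2.64 after another background correction, normexp (adjusted p = 0.00202).

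Of 26 measured genes of DNA replication and S phase, 18 rose against normal thyroid and none fell, and 19 rose when adjusted over the list alone. The mean change was 1.41 (adjusted p = 9.77e-09, and 0.00265 with an estimated correlation). CDC6, which licenses replication origins, rose by 3.34 ± 0.48, UHRF1 by 2.59 ± 0.29 and the sliding clamp gene PCNA by 1.28 ± 0.19. DNA damage repair genes rose as a list, by a mean of 0.81 (8 of 16 members, 9 over the list alone, adjusted p = 0.00383, and 0.0237 with an estimated correlation). H2AX rose by 2.03 ± 0.35 and TIMELESS by 1.82 ± 0.31. The list of G1 to S control genes had a mean change of 0.74 and did not pass (adjusted p = 0.144), although 6 of its 14 members rose and 1 fell.

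Thyroid differentiation genes fell in ATC with a mean change of -3.18, with 8 of 9 measured members lower and all 9 lower over the list alone (adjusted p = 4.37e-06, and 0.0271 with an estimated correlation). TG, which encodes the hormone precursor thyroglobulin, changed by -3.20 ± 0.80 (adjusted p = 0.00476), and the thyroid transcription factor gene PAX8 changed by -2.53 ± 0.65 (adjusted p = 0.00572). The matrix protein gene MATN2 had the largest fall among named genes with separate groups, at -5.81 ± 0.42 (adjusted p = 4.02e-08). TG did not pass in the authors' value table (-1.86, adjusted p = 0.0524), after median centring of each array (-1.97, adjusted p = 0.0646) or with the normal arrays averaged (adjusted p = 0.230). Epithelial adhesion and keratin genes fell with a mean change of -1.57, with 12 of 19 lower and 1 higher, both over all features and over the list alone (adjusted p = 9.26e-06, and 0.0680 with an estimated correlation). CDH1, which encodes E-cadherin, changed by -4.77 ± 0.36 (adjusted p = 4.3e-08), the adhesion gene EPCAM by -4.55 ± 0.45 and the tight junction gene OCLN by -3.72 ± 0.52. The tissue signal of EPCAM was above background on 3 of the 5 ATC arrays and that of CDH1 on 4.

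Genes known as markers of papillary carcinoma were also higher in ATC than in normal thyroid, by a mean of 1.58 (7 of 21 members, 7 over the list alone, adjusted p = 0.000345), but not past the threshold with an estimated correlation (adjusted p = 0.227). LGALS3, which encodes galectin-3, rose by 4.59 ± 0.45, the fibronectin gene FN1 by 4.46 ± 0.81 and the phosphatase gene DUSP5 by 3.75 ± 0.64. MET differed by 0.45 ± 0.75 (adjusted p = 0.669) and KRT19 by 1.02 ± 1.04 (adjusted p = 0.472). The epithelial to mesenchymal transition list rose by a mean of 1.24 (5 of 12 members, 6 over the list alone, adjusted p = 0.0107), with adjusted p = 0.0525 with an estimated correlation. LGALS1 rose by 1.78 ± 0.35 in it, whereas the mesenchymal filament gene VIM differed by 0.36 ± 0.69 (adjusted p = 0.715).

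Hypoxia and glycolysis genes rose by a mean of 1.20 (13 of 22 members, with 1 lower, and 14 over the list alone, adjusted p = 0.000137), with adjusted p = 0.0680 with an estimated correlation. The collagen-modifying enzyme gene P4HA2 rose by 2.35 ± 0.26, the glucose transporter gene SLC2A1 by 2.78 ± 0.67 and the carbonic anhydrase gene CA12 by 3.45 ± 0.82. Interferon response genes rose by a mean of 1.21 (6 of 20 members, 6 over the list alone, adjusted p = 0.00937), with adjusted p = 0.406 with an estimated correlation, and ISG15 rose by 2.76 ± 0.51. Proteasome and unfolded protein response genes rose by 0.46 (11 of 27 higher and 2 lower, 13 and 3 over the list alone, adjusted p = 0.00978), with adjusted p = 0.235 with an estimated correlation. The proteasome subunit gene PSMA5 rose by 1.54 ± 0.22.

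Among markers of other cell types, those of macrophages and other myeloid cells rose in ATC by a mean of 1.58 (7 of 13 members, 7 over the list alone, adjusted p = 0.00937), with adjusted p = 0.204 with an estimated correlation. The Fc receptor gene FCGR2A rose by 4.26 ± 0.89 and the lysosomal marker CD68 by 2.36 ± 0.49. Endothelial markers had a mean change of -0.99 and did not pass as a list (adjusted p = 0.117), with 5 of 14 lower and 1 higher. The receptor gene FLT1 fell by 3.94 ± 0.80, and ENG was the member that rose, by 1.72 ± 0.32. Markers of fibroblasts (mean change 0.58, adjusted p = 0.517) and of T and NK cells (0.86, adjusted p = 0.191) did not pass as lists.

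The other lists did not pass the camera test against normal thyroid. Their mean changes were 0.95 for collagens and extracellular matrix (adjusted p = 0.143), 1.02 for matrix proteolysis (0.0613), 0.25 for the MAPK and immediate early response (0.286), 0.09 for p53 target genes (0.858) and 1.00 for inflammatory cytokines (0.107). They were 0.99 for MHC genes (0.234), -0.09 for ribosomal proteins (0.725), -0.25 for metallothioneins (0.839), 1.09 for B and plasma cells (0.144), -0.33 for smooth muscle and pericytes (0.694), 0.73 for skeletal muscle (0.101), -0.94 for adipocytes (0.329) and 1.23 for squamous epithelium (0.430). The oxidative phosphorylation list had a mean of -0.12 and a median of 0.01 (0.657). Some single members of these lists changed: SPP1, which encodes the matrix protein osteopontin, rose by 5.50 ± 0.98, the protease inhibitor gene TIMP1 by 3.23 ± 0.71 and MYC by 2.04 ± 0.56. NDUFA5, a subunit of complex I, fell by 1.84 ± 0.22 and the immediate early gene FOS fell by 3.22 ± 0.81. Lists with fewer than 3 measured members were not tested: the neutrophil marker FPR1 rose by 3.69 ± 0.95, the C cell marker SCG3 differed by 0.55 ± 0.31 (adjusted p = 0.180), and of 2 red blood cell markers HBA2, whose clone can also bind its near-identical paralog, fell by 3.18 ± 0.81.

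Against normal thyroid, 651 features rose and 623 fell at least 2-fold in ATC, and 2090 features had no overlap between the arrays of both groups (34.5%). For a feature measured on every array, chance gives 1.59% if the normal arrays are independent samples. It gives more with missing values or if the normal arrays are repeats of 1 donor. Clones of ARL3, DGKZ, GID8, SERPINH1 and STX3 passed the test in opposite directions, 5 of the 58 genes with several passing clones. With the normal arrays averaged into 1 sample, 106 features rose and 130 fell, CDH1 and PBK among them. Leaving out 1 array gave between 1655 and 2182 changed features, the lowest without normal 2.

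**Figure D1:**
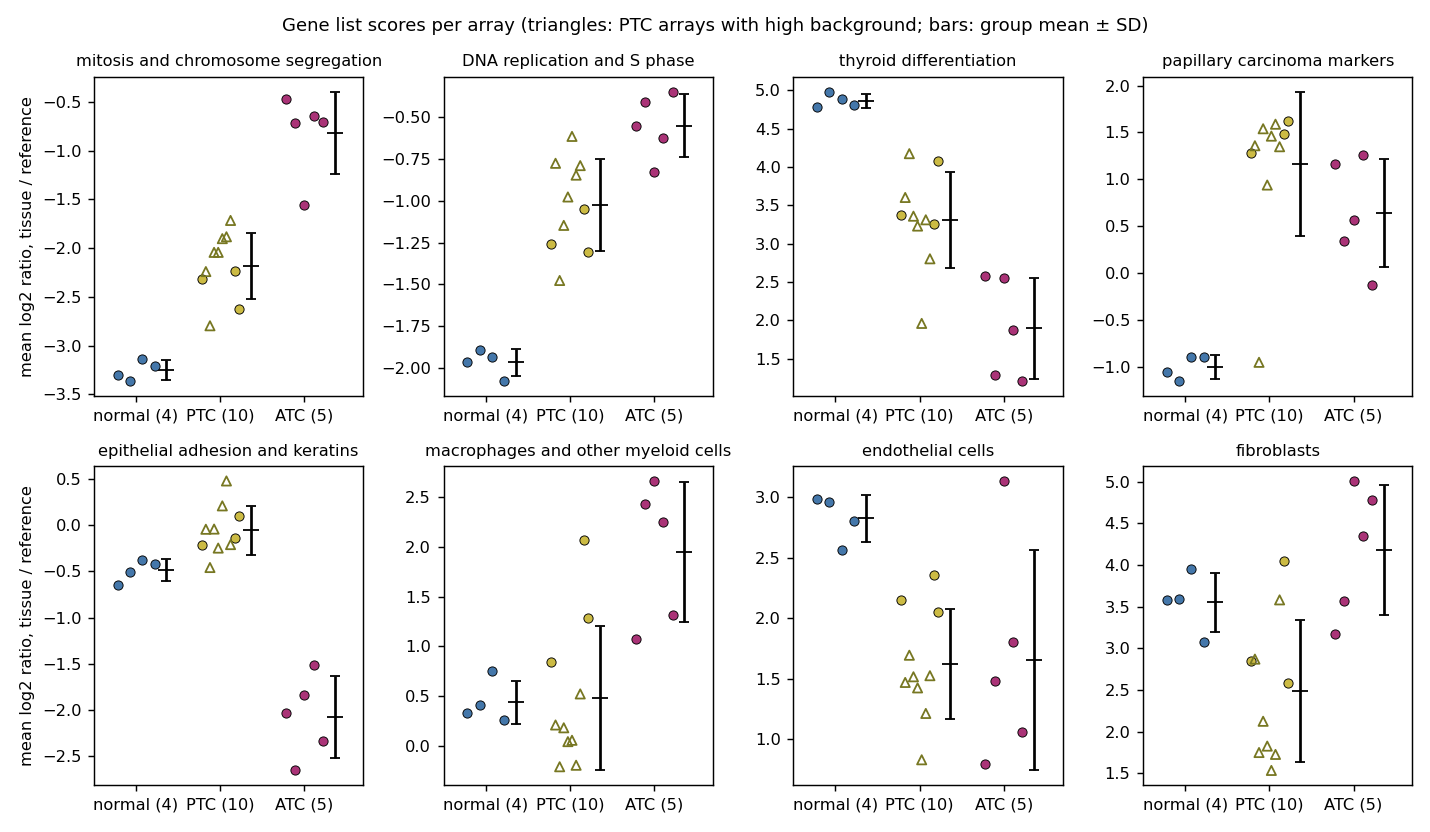
Scores of 8 gene lists per array, as the mean log2 ratio of tissue over reference of the measured members (vertical axis), for 4 normal thyroids, 10 PTC and 5 ATC (horizontal axis). Points are arrays, triangles are the 7 PTC arrays with high background, and bars give the group mean ± SD; the mitosis score was -3.25 in normal thyroid, -2.18 in PTC and -0.82 in ATC.

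In PTC, the known markers of papillary carcinoma were far higher than in normal thyroid, and genes of mitosis and DNA replication were also higher. The mean of the papillary carcinoma markers was 1.17 ± 0.77 (SD, n = 10) in PTC, a difference of 2.17 from normal thyroid (SD 0.13, n = 4), although 1 PTC array had a score within the range of the normal arrays. The mitosis score was -2.18 ± 0.34 (SD, n = 10) in PTC, and its list and that of thyroid differentiation did not pass with an estimated correlation (adjusted p = 0.101 and 0.0942). Thyroid differentiation genes were lower as a list, with a score of 3.31 ± 0.63 (SD, n = 10), while TG itself differed by -0.34 ± 0.71 with all arrays (adjusted p = 0.790) and by 1.16 with the low background arrays (adjusted p = 0.440). With all arrays 519 features rose and 462 fell among 6058, and with the low background arrays 199 rose and 143 fell.

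The papillary carcinoma markers rose in PTC by a mean of 2.24, with 17 of 21 members higher and none lower, and 19 higher over the list alone (adjusted p = 2.01e-15, and 0.0332 with an estimated correlation). With the low background arrays their mean change was 2.48 (adjusted p = 7.2e-23). DPP4, a membrane peptidase gene, rose by 4.46 ± 0.84 (adjusted p = 0.00192) and FN1 by 4.40 ± 0.71 (adjusted p = 0.000709). Of the 63 named genes followed in PTC versus normal thyroid, from all lists, 10 no longer passed after normexp and 3 newly passed. The transcription cofactor gene CITED1 rose by 3.50 ± 0.46, LRP4 by 3.47 ± 0.65, and MET, which encodes the receptor of hepatocyte growth factor, by 3.20 ± 0.66 (adjusted p = 0.00326). LGALS3 rose by 1.94 ± 0.39 (adjusted p = 0.00288). KRT19 differed by 2.52 ± 0.92 (adjusted p = 0.0687), and it passed without ATC 4 (0.0102) or without PTC 3 (0.0276). Beyond this list, the secreted protein gene AGR2 rose by 3.57 ± 0.46, the transporter gene ABCC3 by 3.44 ± 0.48 and the receptor gene IL1RAP by 3.43 ± 0.39.

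Of the 43 mitosis genes, 22 rose in PTC and 1 fell against normal thyroid, and 29 rose and 1 fell over the list alone. Their mean change was 1.05 (adjusted p = 2.27e-11), with adjusted p = 0.101 with an estimated correlation. The mean was 0.86 with the low background arrays (adjusted p = 2.33e-10), with 10 members higher. The centromere protein gene CENPF rose by 2.49 ± 0.36 and the kinase gene AURKB by 2.40 ± 0.44. KIF23 and BUB1 were not above background on any normal array, and on 5 and 4 of the 10 PTC arrays; their rise was at least 4.18-fold and at least 3.10-fold (adjusted p = 0.00242 and 0.00469). PLK1 differed by 1.60 ± 0.67 (adjusted p = 0.114, and 0.0477 without PTC 10; 0.82 with the low background arrays, adjusted p = 0.350) and the brightest AURKA clone by 0.08 ± 0.26 (adjusted p = 0.859). The mean of all AURKA clones differed by 0.61 (adjusted p = 0.0611), and AURKA rose by 1.67 after normexp (adjusted p = 0.0205). DNA replication genes rose by a mean of 0.89 (11 of 26 members, 14 over the list alone, adjusted p = 4.17e-06, and 0.0143 with an estimated correlation), and by 0.78 with the low background arrays (4 members higher, adjusted p = 1.13e-06). RRM2, a subunit of ribonucleotide reductase, rose by 2.41 ± 0.59 and CDC6 by 2.26 ± 0.42. PCNA rose by 0.74 ± 0.17 (adjusted p = 0.00577), and its difference of 0.67 with the low background arrays did not pass (adjusted p = 0.127).

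Thyroid differentiation genes fell in PTC with a mean change of -1.79, with 3 of 9 members lower, both over all features and over the list alone (adjusted p = 1.29e-05), with adjusted p = 0.0942 with an estimated correlation. The mean change with the low background arrays was -1.58 (adjusted p = 5.11e-07). MATN2 fell by 3.77 ± 0.35 (adjusted p = 7.74e-06) and the trefoil factor gene TFF3, measured on 5 of 10 PTC arrays, fell by 4.49 ± 0.79. PAX8 differed by -0.93 ± 0.54 (adjusted p = 0.260). Outside the lists, ADD2, which encodes a membrane skeleton protein, fell by 4.61 ± 0.93 on the 6 PTC arrays that measured it.

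Genes of p53 targets rose by a mean of 0.60 (3 of 16 members, 8 over the list alone, adjusted p = 0.00646), with adjusted p = 0.101 with an estimated correlation, and by 0.56 with the low background arrays (1 member, adjusted p = 0.00588); the death receptor gene FAS rose by 1.97 ± 0.33. Genes of the MAPK and immediate early response rose by 0.56 (6 of 25 members, 7 over the list alone, adjusted p = 0.0141), with adjusted p = 0.458 with an estimated correlation, and their mean of 0.24 with the low background arrays did not pass (adjusted p = 0.221). The MAPK phosphatase genes DUSP5 and DUSP6 rose by 2.57 ± 0.57 and 2.43 ± 0.47. Hypoxia and glycolysis genes rose by 0.65 (6 of 22 members, 6 over the list alone, adjusted p = 0.00764), with adjusted p = 0.244 with an estimated correlation, and had a mean of 0.44 with the low background arrays (adjusted p = 0.141). P4HA2 rose in both, by 2.24 ± 0.23 with all arrays. The cell cycle gene CCND1, a member of the MAPK list and of the papillary carcinoma markers, rose by 1.80 ± 0.26. Its list of G1 to S control genes did not pass. The adhesion receptor gene CD44 rose by 1.42 ± 0.34 and the catenin gene CTNNB1 by 1.23 ± 0.23, but their lists did not pass.

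Metallothionein genes fell in PTC with a mean change of -2.47 (5 of 6 members, 5 over the list alone, adjusted p = 1.71e-05), with adjusted p = 0.238 with an estimated correlation. The low background arrays gave a mean of -1.47 (adjusted p = 0.0246), with no single member past the threshold. MT1H, whose clone can bind other members of its near-identical family, fell by 3.31 ± 0.66 with all arrays and differed by -1.92 with the low background arrays (adjusted p = 0.145). Endothelial markers fell with a mean change of -1.10 (5 of 14 lower and 1 higher, 8 and 1 over the list alone, adjusted p = 0.00744), with adjusted p = 0.238 with an estimated correlation. Fibroblast markers fell by 1.05 (2 of 13 members, 2 over the list alone, adjusted p = 0.0395), with adjusted p = 0.426 with an estimated correlation. Neither passed with the low background arrays, where the means were -0.63 (adjusted p = 0.118) and -0.36 (adjusted p = 0.482). The fibroblast receptor gene PDGFRA fell by 3.90 ± 0.80 with all arrays and differed by -1.88 with the low background arrays (adjusted p = 0.242). Ribosomal protein genes fell by 0.35 (4 of 22 members, 4 over the list alone, adjusted p = 0.0141), with adjusted p = 0.426 with an estimated correlation and a mean of -0.24 with the low background arrays (adjusted p = 0.104).

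The interferon response, MHC and macrophage lists did not pass in PTC with all arrays (adjusted p = 0.722, 0.628 and 0.391) and had mean changes of -0.01, 0.23 and 0.20. With the low background arrays they rose, by 1.05 (2 of 20 members, adjusted p = 0.000358), 1.16 (0 of 9 members, adjusted p = 0.0185) and 1.01 (1 of 13 members, adjusted p = 0.0213), but none of them passed with a correlation estimated from those arrays (adjusted p = 0.389 for each). The exact permutation p of their scores on 3 PTC and 4 normal arrays was 0.0286, 0.0571 and 0.0286, where 0.0286 is the smallest possible. The macrophage-associated apolipoprotein gene APOC1 rose in both, by 2.90 ± 0.50 with all arrays. The epithelial to mesenchymal transition and oxidative phosphorylation lists did not pass with all arrays, at 0.08 and -0.22 (adjusted p = 0.416 and 0.0608), but passed with the low background arrays, at 0.47 (adjusted p = 0.0388) and -0.31 (adjusted p = 0.00588), without passing there at an estimated correlation (adjusted p = 0.252 and 0.0921). The median and the mean had opposite signs for the interferon list (median 0.05), inflammatory cytokines (mean 0.26, median -0.12) and T and NK cells (mean 0.03, median -0.01), and the test of squamous epithelium pointed down at a mean of 0.06. None of the last 3 lists passed (adjusted p = 0.996, 0.969 and 0.969). The other lists did not pass in PTC: mean changes were 0.50 for G1 to S control (adjusted p = 0.0608), 0.33 for DNA repair (0.101), 0.47 for epithelial adhesion and keratins (0.118), -0.47 for collagens (0.236), 0.18 for matrix proteolysis (0.575) and 0.13 for the proteasome and unfolded protein response (0.391). They were 0.71 for B and plasma cells (0.212), -0.47 for smooth muscle and pericytes (0.416), 0.13 for skeletal muscle (0.575) and -0.83 for adipocytes (0.284). Among genes named in every comparison, CDH1 differed by -0.25 ± 0.32 (adjusted p = 0.643) and VIM by -1.69 ± 0.61 (adjusted p = 0.0654). VIM passed without PTC 1, PTC 9 or PTC 10, which are the 3 low background PTC arrays, and with the low background arrays its sign turned, to 0.20 (adjusted p = 0.829). TIMP1 rose by 1.88 ± 0.62 (adjusted p = 0.0457), but did not pass with the low background arrays (1.95, adjusted p = 0.0695) or when any 1 of the 4 normal arrays, 8 of the PTC arrays (1, 2 and 4 to 9) or ATC 4 was left out, with adjusted p between 0.0524 and 0.138.

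The authors' value table, whose PTC columns mostly match no array file, gave other sizes for the PTC lists when each column was centred on its median and the same features were used. Mitosis genes had a mean change of 0.37 there (adjusted p = 0.00233) and replication genes of 0.50 (adjusted p = 5.67e-05). Thyroid differentiation genes had a mean change of -0.96 and did not pass (adjusted p = 0.0638), although they passed among all features of the value table (-0.87, adjusted p = 0.0270). Fibroblast markers turned to 0.14 (adjusted p = 0.660), and endothelial markers, at -0.11, and ribosomal proteins, at -0.14, did not pass (adjusted p = 0.752 and 0.315). Hypoxia genes were at 0.36 (adjusted p = 0.0410) and metallothioneins at -0.95 (adjusted p = 0.0494). Lists that passed in the value table and not with the array files were the epithelial to mesenchymal transition (0.70, adjusted p = 0.00233), macrophages (0.98, adjusted p = 0.00461), interferon response (0.52, adjusted p = 0.0177), oxidative phosphorylation (-0.18, adjusted p = 0.0262), collagens (0.64, adjusted p = 0.0385), DNA repair (0.26, adjusted p = 0.0494) and matrix proteolysis (0.67, adjusted p = 0.0494).

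Against normal thyroid, 326 features rose and 254 fell at least 2-fold in PTC, and 753 had no overlap between groups (12.4%). For a feature measured on every array, chance gives 0.200% if the normal arrays are independent samples, and more if they are repeats of 1 donor. With missing values chance gives more. None of the 15 genes with several passing clones had clones of opposite direction. Of the 981 changed features, 283 also passed with the low background arrays and 976 kept their sign in them, although they are part of the same arrays. With 3 instead of 10 PTC arrays the test has less power, so a lost call alone does not show a dependence on background. The count was 600, 563, 581 and 636 without normal 1, 2, 3 and 4 and reached 1082 without PTC 10. With the normal arrays averaged into 1 sample, a single feature passed, a clone without a gene name in the platform annotation that fell by 4.37 ± 0.25 in PTC with all arrays and that was singled out after its values were seen.

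**Figure D2:**
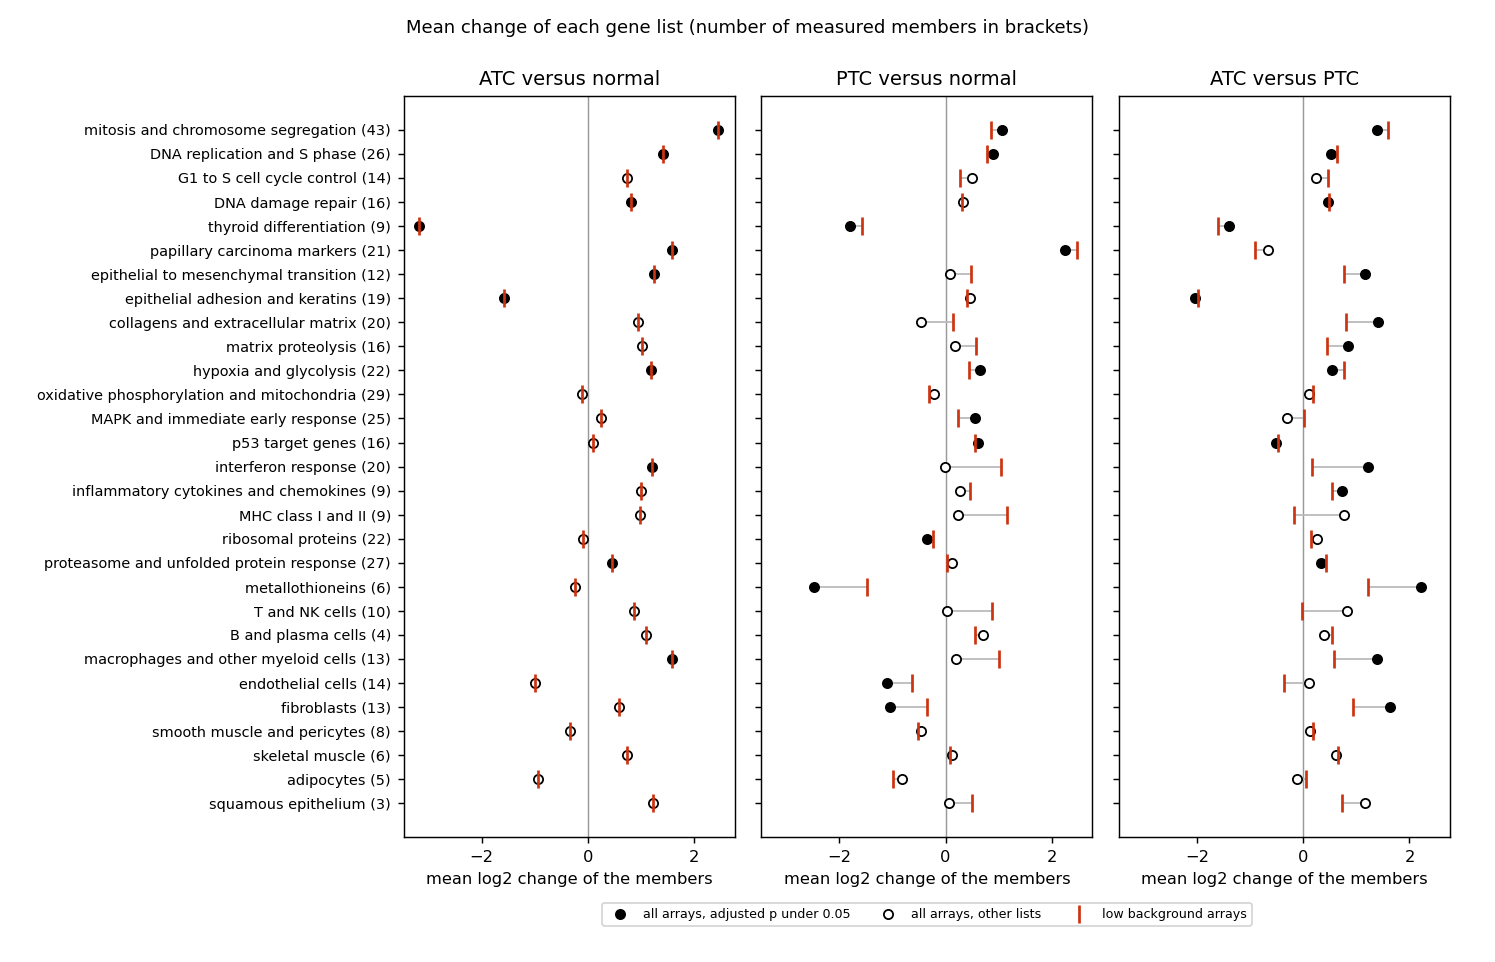
Mean log2 change of the measured members of 29 gene lists (horizontal axis) in each of 3 comparisons, with the number of members in brackets beside the list's name. Filled points passed with all 19 arrays, open points did not, and red ticks give the mean with the 12 low background arrays; the fibroblast mean moved from -1.05 to -0.36 in PTC versus normal.

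Set directly against PTC, ATC had lower epithelial adhesion genes and higher mitosis genes. The mean of the epithelial adhesion and keratin list was -0.06 ± 0.27 (SD, n = 10) in PTC and -2.08 ± 0.44 (SD, n = 5) in ATC, and every ATC array lay below every PTC array (exact permutation p = 0.000333, adjusted p = 0.00724 over 87 list tests, the smallest p these group sizes allow). The mitosis score differed by 1.36 with the same p. Genes of hypoxia, the proteasome and DNA replication were also higher in ATC at the preset correlation, and several papillary carcinoma markers were lower. With an estimated correlation the epithelial list passed, and those of mitosis, hypoxia, the proteasome and replication did not (adjusted p = 0.0776, 0.269, 0.269 and 0.0776). In all, 1003 features rose and 1048 fell among 6058, and with the low background arrays 461 rose and 548 fell.

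Of the 19 epithelial adhesion and keratin genes, 14 fell in ATC against PTC and none rose, and 15 fell over the list alone. The mean change was -2.04 (adjusted p = 2.72e-13, and 0.0234 with an estimated correlation) and -1.97 with the low background arrays (adjusted p = 2.12e-09, and 0.0859 with a correlation estimated from them). EPCAM changed by -4.64 ± 0.36 (adjusted p = 6.89e-08), CDH1 by -4.52 ± 0.30 (adjusted p = 7.18e-09) and OCLN by -4.00 ± 0.44. MPZL2, an adhesion molecule of epithelia, changed by -4.12 ± 0.46 and the exocytosis gene STXBP6, above background on 2 of 5 ATC arrays, by -4.49 ± 0.57.

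Mitosis genes rose in ATC against PTC by a mean of 1.40, with 33 of 43 members higher and 1 lower, and 35 and 2 over the list alone (adjusted p = 6.29e-14), with adjusted p = 0.0776 with an estimated correlation. The low background arrays gave 1.59 (adjusted p = 5.86e-24). CEP55 rose by 3.55 ± 0.38, PBK by 3.38 ± 0.37, the spindle checkpoint kinase gene TTK by 2.81 ± 0.49 and BUB1 by 2.29 ± 0.47. After normexp, 28 of the 67 named genes followed in ATC versus PTC, from all lists, no longer passed and 1 newly passed. PLK1 rose by 1.73 ± 0.62 (adjusted p = 0.0403), but did not pass without ATC 1, 2, 4 or 5 or without PTC 1, 2, 3, 4 or 10, with adjusted p between 0.0523 and 0.0829. The brightest AURKA clone differed by -0.04 ± 0.24 (adjusted p = 0.907), whereas the mean of all AURKA clones rose by 0.97 (adjusted p = 0.00128). DNA replication genes rose by 0.52 (10 of 26 higher and 1 lower, 11 and 1 over the list alone, adjusted p = 0.00365), with adjusted p = 0.0776 with an estimated correlation, and by 0.63 with the low background arrays (adjusted p = 0.00165). This list did not pass after normexp, at 0.22 (adjusted p = 0.191). UHRF1 rose by 1.92 ± 0.24, RRM1 by 1.42 ± 0.31, MCM6 by 1.32 ± 0.28 and PCNA by 0.55 ± 0.15 (adjusted p = 0.0107). PCNA differed by 0.61 with the low background arrays, without passing (adjusted p = 0.0918). MYC rose by 3.01 ± 0.46 while its list of G1 to S control genes did not pass (mean 0.23, adjusted p = 0.798). DNA repair genes rose by 0.47 (4 of 16 higher and 1 lower, 5 and 1 over the list alone, adjusted p = 0.0352), with adjusted p = 0.0776 with an estimated correlation, and by 0.49 with the low background arrays (1 member, adjusted p = 0.0309). FANCI rose by 1.14 ± 0.18.

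Thyroid differentiation genes fell further in ATC than in PTC, with a mean change of -1.39 (5 of 9 members, 5 over the list alone, adjusted p = 0.0278), with adjusted p = 0.247 with an estimated correlation. The mean change with the low background arrays was -1.61 (adjusted p = 0.00311). The list did not pass without ATC 2, at -1.23 (adjusted p = 0.0634), nor after normexp, at -0.91 (adjusted p = 0.139). TG fell by 2.86 ± 0.66 (adjusted p = 0.00277; fell by 4.36 with the low background arrays) but did not pass after normexp (-2.33, adjusted p = 0.201), and MATN2 fell by 2.04 ± 0.35. PAX8 fell by 1.60 ± 0.54 (adjusted p = 0.0295), but did not pass without ATC 2 (0.140) or ATC 3 (0.0922). Papillary carcinoma markers had a mean change of -0.66 (adjusted p = 0.144), with 9 of 21 lower and 3 higher, and had a mean change of -0.90 with the low background arrays (adjusted p = 0.0380). With an estimated correlation the list did not pass with all arrays or with the low background arrays (adjusted p = 0.558 and 0.375). CITED1 changed by -3.58 ± 0.46, LRP4 by -3.17 ± 0.60, DPP4 by -2.76 ± 0.78 and MET by -2.75 ± 0.61 (adjusted p = 0.00222), whereas LGALS3 rose by 2.65 ± 0.36 and FN1 differed by 0.06 ± 0.66 (adjusted p = 0.957). KRT19 differed by -1.51 ± 0.85 (adjusted p = 0.180, and 0.00446 without ATC 4).

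Hypoxia and glycolysis genes rose in ATC against PTC by a mean of 0.55 (7 of 22 higher and 1 lower, 8 and 1 over the list alone, adjusted p = 0.0151), with adjusted p = 0.269 with an estimated correlation, and by 0.76 with the low background arrays (adjusted p = 0.00165). The glycolytic enzyme genes ENO1 and LDHA rose by 1.82 ± 0.21 and 1.55 ± 0.23, whereas VEGFA, which encodes a vascular growth factor, fell by 1.44 ± 0.40. Proteasome and unfolded protein response genes rose by 0.33 (10 of 27 higher and 1 lower, 13 and 1 over the list alone, adjusted p = 0.0151), with adjusted p = 0.269 with an estimated correlation, and by 0.43 with the low background arrays (5 members, adjusted p = 0.00475); PSMD2 rose by 1.40 ± 0.21. Genes of p53 targets fell by 0.52 (6 of 16 lower, 7 lower and 1 higher over the list alone, adjusted p = 0.0352), with adjusted p = 0.247 with an estimated correlation, and RRM2B fell by 1.59 ± 0.25. Their mean of -0.47 with the low background arrays did not pass (adjusted p = 0.107). The complex II gene SDHA fell by 0.89 ± 0.12 with a list that did not pass (mean 0.10, adjusted p = 0.327); without background correction its difference was 0.0040, and the mean of all its clones did not pass (-0.26, adjusted p = 0.0963).

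Stromal, immune and metallothionein lists were higher in ATC than in PTC with all arrays, but none of the following 8 lists passed with the low background arrays. Collagens and extracellular matrix rose by 1.41 (9 of 20 members, 11 over the list alone, adjusted p = 0.00474, and adjusted p = 0.269 with an estimated correlation), against 0.80 with the low background arrays (adjusted p = 0.138). Fibroblast markers rose by 1.63 (6 of 13, 6 over the list alone, adjusted p = 0.0137, and adjusted p = 0.269 with an estimated correlation), against 0.94 (adjusted p = 0.176). Metallothioneins rose by 2.22 (6 of 6, 6 over the list alone, adjusted p = 0.00365, and adjusted p = 0.269 with an estimated correlation), against 1.22 (adjusted p = 0.138). The interferon response rose by 1.22 (8 of 20, 13 over the list alone, adjusted p = 0.00474, and adjusted p = 0.320 with an estimated correlation), against 0.16 (adjusted p = 0.585). Macrophage markers rose by 1.39 (8 of 13, 8 over the list alone, adjusted p = 0.0191, and adjusted p = 0.269 with an estimated correlation), against 0.57 (adjusted p = 0.195). Inflammatory cytokines rose by 0.73 (3 of 9, 3 over the list alone, adjusted p = 0.0332, and adjusted p = 0.269 with an estimated correlation), against 0.54 (adjusted p = 0.192). The epithelial to mesenchymal transition list rose by 1.15 (6 of 12, 8 over the list alone, adjusted p = 0.0151, and adjusted p = 0.0776 with an estimated correlation), against 0.77 (adjusted p = 0.0824). Matrix proteolysis rose by 0.84 (4 of 16, 4 over the list alone, adjusted p = 0.0430, and adjusted p = 0.278 with an estimated correlation), against 0.45 (adjusted p = 0.192). COL6A3, a collagen of fibroblasts, rose by 3.42 ± 0.58 with all arrays and by 3.03 with the low background arrays, the chemokine gene CCL5 by 1.75 ± 0.24 and 1.64, and LGALS1 by 1.82 ± 0.29 and 1.10. VIM rose by 2.05 ± 0.56 (adjusted p = 0.00913), but differed by 0.16 with the low background arrays (adjusted p = 0.810) and by -0.073 in the authors' value table, and FCER1G rose by 4.16 ± 0.88 but differed by 1.61 (adjusted p = 0.272). TIMP1 differed by 1.34 ± 0.58 (adjusted p = 0.0790).

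None of these 8 lists passed in the centred value table either, where the means were 0.15 for collagens (adjusted p = 0.790), 0.29 for fibroblasts (0.774), 0.75 for metallothioneins (0.354), 0.55 for the interferon response (0.117), 0.39 for macrophages (0.261), 0.61 for cytokines (0.250), 0.48 for the epithelial to mesenchymal transition (0.207) and 0.34 for matrix proteolysis (0.354). The p53 target genes, at -0.40, did not pass there (adjusted p = 0.0503). DNA replication genes rose by 0.83 in the value table, hypoxia genes by 0.90 and proteasome genes by 0.54 (adjusted p = 1.70e-05, 0.000102 and 0.000419).

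Endothelial markers did not pass as a list between ATC and PTC (mean 0.11, adjusted p = 0.923), with a mean of -0.36 with the low background arrays and a fall in the value table (mean change -0.92, adjusted p = 0.0440). The mean and the median of adipocyte markers had opposite signs (-0.12 and 0.16, adjusted p = 0.798). The mean changes of the remaining lists, none of which passed, were -0.31 for the MAPK and immediate early response (adjusted p = 0.587), 0.76 for MHC genes (0.277), 0.26 for ribosomal proteins (0.125), 0.83 for T and NK cells (0.0824), 0.38 for B and plasma cells (0.513), 0.13 for smooth muscle and pericytes (0.848), 0.61 for skeletal muscle (0.0871) and 1.16 for squamous epithelium (0.323). The neutrophil marker FPR1, from a list too short to test, rose by 3.69 ± 0.78 with all arrays but did not pass with the low background arrays (adjusted p = 0.221). At least 2-fold, 470 features rose and 483 fell, and 560 had no overlap between groups (9.24%). Chance gives 0.0666% for a feature measured on every array, and more with missing values. Clones of GID8, LIG4, POLR1D and SELENOW passed in opposite directions, 4 of the 55 genes with several passing clones. Of the 2051 changed features, 855 also passed with the low background arrays and 2030 kept their sign in them, although they are part of the same arrays. Leaving out 1 array gave between 1731 and 2127 changed features. The count was 862 after normexp background correction, and 1644 when only the ATC and PTC arrays were fitted. The fit over all 3 groups also takes its spread from the normal arrays, which varied least.

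**Figure D3:**
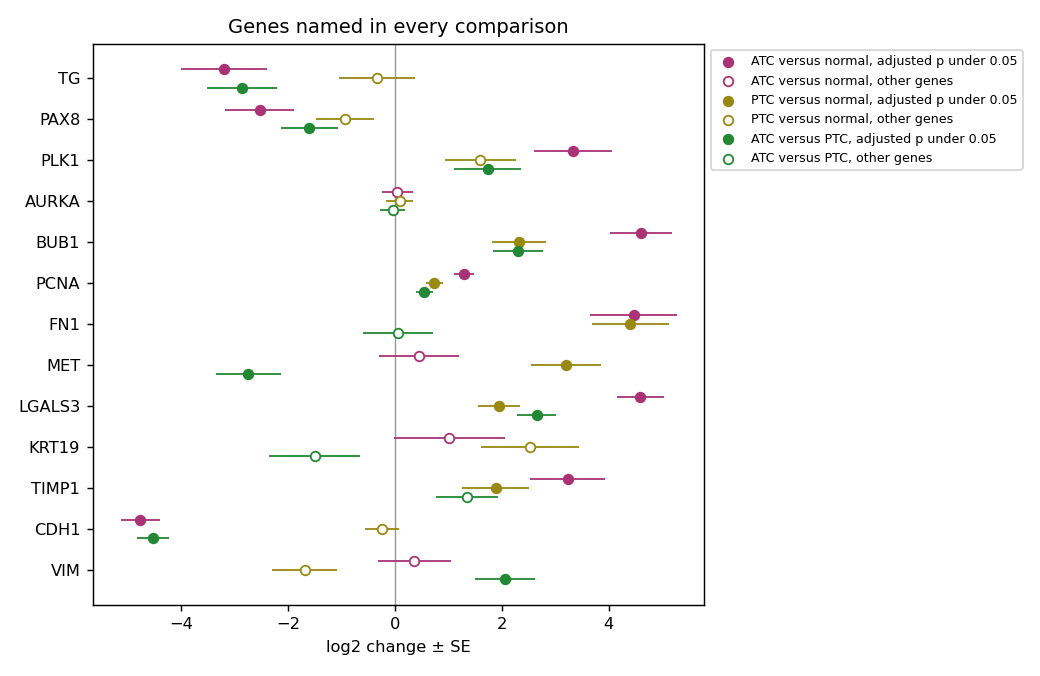
Log2 change with its standard error (horizontal axis) of the 13 measured genes that were named in every comparison by a rule set beforehand (vertical axis), in colour by comparison. Filled points passed at an adjusted p below 0.05; CDH1 changed by -4.77 in ATC versus normal and by -0.25 in PTC versus normal, and MET by 0.45 and 3.20.

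Many changes against normal thyroid were shared by both cancers. In ATC and PTC alike 314 features rose and 252 fell, and 16 changed in opposite directions, among 6058 tested in both. With the low background arrays 147 rose and 116 fell in both, and with the normal arrays averaged into 1 sample a single feature passed in PTC, so at most 1 could be shared. Independent lists of the same sizes would share 89.1 higher and 83.5 lower features. Unchanged groups set against the same 4 normal arrays shared at most 1 in 100 simulations. Such groups have few calls to share, so that count cannot tell how far the shared normal arrays raised the overlap. The changes correlated over features with r = 0.562, where simulated unchanged groups gave a median r of 0.656, and the covariance was 0.446 against a simulated 0.0962. With the normal arrays split into pairs, 1 pair for each cancer, between 106 and 159 features changed alike in both, and the covariance stayed between 0.412 and 0.426. Of the features shared in direction, 153 changed further in ATC by the test of ATC against PTC. There were 250 features that changed in PTC and differed the opposite way between ATC and PTC, and 872 that changed in ATC against normal thyroid with no call between ATC and PTC.

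Of the 29 lists tested, 11 passed in ATC against normal thyroid, 11 in PTC against normal thyroid and 16 in ATC against PTC. With a correlation between genes estimated from these arrays 4, 2 and 1 passed, and with the rotation test fry 20, 15 and 21 passed. Exact permutation of the array scores, which asks whether a list differs rather than whether it differs more than other genes, passed for 17, 13 and 17 lists (adjusted over 87 tests). In ATC against normal thyroid these included 7 lists that camera did not call: G1 to S control (adjusted p = 0.0223), B and plasma cells (0.0223), skeletal muscle (0.0329), and collagens, matrix proteolysis, cytokines and adipocytes (0.0450 each). The interferon response, called by camera, did not pass (adjusted p = 0.0649). In PTC against normal thyroid they included G1 to S control (0.0124), B and plasma cells (0.0124), adipocytes (0.0217), epithelial adhesion (0.0248) and DNA repair (0.0282), and the MAPK response (0.144), ribosomal proteins (0.0542) and fibroblasts (0.0635), called by camera, did not pass. In ATC against PTC all 16 lists called by camera passed, and skeletal muscle with them (adjusted p = 0.0487).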

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

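The rule for extreme samples was set before the data were examined, and no further test was chosen after the result was seen. In each group of 4, 5 or 10 arrays, over the arrays that measured the gene or list, the gap between the most extreme array and its nearest neighbour was divided by the group's range and set against Dixon's 95% critical value. It was applied to list scores and to named genes in 438 tests, and 37 passed, against 21.9 expected by chance at 1 in 20. List scores gave 6 of them in 87 tests and genes 31 in 351.

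Among the normal arrays, the lowest array lay apart for the oxidative phosphorylation list (0.940). The genes with a lowest array apart were ADD2 (0.889), ALAS2 (0.870), CD34 (0.981), CITED1 (0.929), FCGR2A (0.868) and KIF23 (0.858). The highest array lay apart for RPL34 (0.991).

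Among the PTC arrays, the lowest array lay apart for the papillary carcinoma markers (0.736). The genes with a lowest array apart were DPP4 (0.735), DUSP6 (0.572), MET (0.567), MPZL2 (0.522), PAX8 (0.536), RRM2 (0.724), TIMP1 (0.679) and TK1 (0.520). An array lay high for the lists of T and NK cells (0.468), skeletal muscle (0.483) and adipocytes (0.485), and for CCND1 (0.633, 9 arrays measured), CD34 (0.544, 9 arrays), COL15A1 (0.506), KRT16 (0.743, 5 arrays) and PLAU (0.576).

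Among the ATC arrays, the lowest array lay apart for the mitosis list (0.774). The genes with a lowest array apart were ANLN (0.725), CENPF (0.711), LGALS3 (0.715), PLAU (0.770), TTK (0.785) and VIM (0.783). An array lay high for AGR2 (0.785), KRT16 (0.730), MPZL2 (0.770), RRM2 (0.863) and SLC4A4 (0.726).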

How the results depend on the processing

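The low background arrays (for single features, lists and the overlap), the background block, the floors, the centred value table and the averaged normal arrays were chosen after the data were examined. Background differences within PTC, the 4 normal arrays that may share a donor (236 and 1 features with the normal arrays averaged), unmatched value columns and an unrecorded batch limit all comparisons with PTC or normal thyroid. The planned batch alternative was not run, since no batch was recorded, and the cause of each shift below was not tested.

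The number of features changed was 2135 in ATC versus normal, 981 in PTC versus normal and 2051 in ATC versus PTC. At least 2-fold it was 1274, 580 and 953, and among features measured in every array 1127, 509 and 1175. With the normal arrays averaged it was 236 and 1 in the first 2 comparisons. With the low background arrays it was 342 for PTC versus normal and 1009 for ATC versus PTC, and with the background block 363 and 1115. With only the 2 groups compared it was 2156 in ATC versus normal, 1202 in PTC versus normal and 1644 in ATC versus PTC. For PTC versus normal it was 2296 with array weights, 1768 without background correction, 473 with the replicate block, 321 in the value table and 543 in the centred value table. For ATC versus PTC it was 862 after normexp. Without 1 array it ranged from 1655 to 2182 in ATC versus normal, 563 to 1082 in PTC versus normal (600, 563, 581 and 636 without normal 1 to 4) and 1731 to 2127 in ATC versus PTC. Without a filter, the median change of all features moved to -0.24 in PTC versus normal and to 0.17 in ATC versus PTC.

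After normexp, the DNA replication and S phase list shift was 0.22 and the thyroid differentiation list shift -0.91 in ATC versus PTC, neither passing (adjusted p = 0.191 and 0.139; over the other alternatives at most 0.0256 and 0.0404). Without 1 array the thyroid differentiation list shift ranged from -1.55 to -1.21 (-1.23 without ATC 2, adjusted p = 0.0634) and the DNA replication and S phase list shift from 0.47 to 0.60. List shifts were followed for the mitosis, DNA replication and thyroid differentiation lists only. In the other alternatives 157 shifts of these 3 lists kept direction and call over the 3 comparisons. The averaged normal arrays hardly touch these tests, which set genes against each other. Of the gene lists, 11, 11 and 16 passed in ATC versus normal, PTC versus normal and ATC versus PTC, and 4, 2 and 1 with an estimated correlation. With the low background arrays 8 passed in ATC versus PTC, and with a correlation estimated from them 3, 3 and 0 (camera; 9, 5 and 6 at an unadjusted p under 0.05). In ATC versus PTC 8 passed in the centred value table. With the low background arrays 263 features changed alike in ATC and PTC against normal, against 566. With split normal arrays the number was 114, 139, 145, 106, 159 and 118.

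In ATC versus PTC, the direction turned for AURKA with the mean of all clones (0.97), for BST2 with the block and with the low background arrays (-0.24), for SDHA without background correction (0.0040), and in the value table, uncentred and centred, for CD34 (-0.59, -0.50), HLA-DRA (-0.34, -0.25) and PLAU (-0.32, -0.22) and, uncentred, for COL15A1 (-0.093) and VIM (-0.073). In PTC versus normal it turned in the value table for COL15A1 (0.13, 0.20) and TIMP3 (0.12, 0.18). The other changes of named genes under these settings were 2877 of the same call (here a sign could turn where neither value passed), 388 no longer passing and 38 newly passing; without 1 array they were 3460, 117 and 14.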

Other observations

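Several changes crossed the borders of the lists. In ATC versus PTC the adhesion genes CDH1, EPCAM, OCLN and MPZL2 were lower, and of the papillary carcinoma markers CITED1, LRP4, DPP4 and MET were lower, whereas LGALS3 was higher by 2.65 and FN1 differed by 0.06. So the marker genes of papillary carcinoma did not move as a block.

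Some genes of a list moved apart in ATC. The immediate early gene FOS fell by 3.22 against normal thyroid while MYC rose by 2.04, and ENG rose by 1.72 while other endothelial genes such as FLT1 fell. VEGFA fell by 1.44 against PTC although the glycolytic genes ENO1 and LDHA rose.

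The splits of the samples and the tests with members above background were planned; the tests with the low background arrays, the dim reference and the macrophage and endothelial scores were chosen after the result was seen. If the 4 normal arrays are independent samples, chance can be excluded for the number of changed features: only the real split (1 of 100) reached it, with 2135 against a highest other of 1465 for ATC versus normal, 981 against 104 for PTC versus normal and 2051 against 52 for ATC versus PTC. If they are repeats of 1 donor, the splits cannot exclude chance for the comparisons with normal thyroid, where averaging them left 236 and 1 features. For the number of lists, only the real split (1 of 100) reached the 16 of ATC versus PTC, where the highest other gave 14. Chance alone is therefore unlikely there. For features and lists alike, the splits cannot separate group from background, since all 7 high background arrays were PTC. In ATC versus PTC 8 lists passed with the low background arrays, and 1 with an estimated correlation. For the number of lists, chance cannot be excluded for ATC versus normal (11 against 18, 22 of 100) or for PTC versus normal (11 against 12, 7 of 100). In the other splits the median number of passing lists was 7 for ATC versus normal, 6 for PTC versus normal and 5 for ATC versus PTC. So lists often passed at the preset correlation when the groups were mixed.

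Fibroblast and endothelial genes were lower in PTC than in normal thyroid, by a mean of -1.08 over 27 members, of which 2 of 13 and 5 of 14 fell and 1 endothelial member rose; neither list passed with an estimated correlation (adjusted p = 0.426 and 0.238). The low background arrays gave -0.50, a difference of 0.577 (SE 0.130 over members, taken as independent). High background on 7 PTC arrays may therefore account for part of the fall. A reference channel near background, which lifts the denominator of the ratio, may add to it: 150 features with a dim reference lay lower with all arrays than with the low background arrays by a median of -0.815 more than 3933 features with a bright one (-0.992 to -0.566 leaving out 1 low background PTC array). Of the fibroblast members 5 of 13 and of the endothelial members 5 of 14 had a dim reference, against 2.48% of all features. A lower stromal share of PTC stays open, but in the authors' value table the mean change was 0.14 for fibroblasts and -0.11 for endothelial cells, so a fall was not seen there.

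Mitosis genes were higher in PTC than in normal thyroid at the preset correlation, but not past the threshold with an estimated correlation (adjusted p = 0.101, and 0.252 with the low background arrays). The tables argue against high background as the cause, since the score of the low background PTC arrays exceeded that of the normal arrays by 0.859, against 1.07 with all PTC arrays, although the mean change in the centred value table was 0.37. The 12 of 43 members above background on every array also rose, by a mean of 0.822 (SE 0.230 over members). That SE takes the members as independent, but the list's estimated correlation was 0.312 with the low background arrays. It is therefore too small to decide whether dim members were the cause. A higher share of dividing cells in PTC is a biological hypothesis found on the same data, and other technical causes, such as a batch that was not recorded, stay open.

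Epithelial adhesion and thyroid differentiation genes were lower in ATC than in normal thyroid, although epithelial adhesion did not pass with an estimated correlation (adjusted p = 0.0680, and 0.157 with the low background arrays). A lower share of thyroid cells with all other cell types raised alike was examined with the macrophage score less the endothelial score. It was 0.29 ± 0.51 (SD, n = 5) in ATC and -2.39 ± 0.39 (SD, n = 4) in normal thyroid. The difference was 2.68 (exact permutation p = 0.00794, the smallest possible). This contrast was chosen after the result was seen in these same arrays, so its p is no independent support. The endothelial score itself differed by -1.17 and did not pass (exact permutation p = 0.0556, with 4 of 5 ATC arrays below all normal arrays and 1 above). At most, these scores speak against all other cell types rising alike, and not against a lower share of thyroid cells. Members too dim to measure are argued against as the whole cause by the 14 of 28 members above background on every array. Their mean change was -1.45 (SE 0.405 over members, taken as independent). A loss of thyroid cells with more macrophages, and a loss of the genes within tumour cells, could both give these values.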
